A study of Mus musculus with 6 samples.

How the data were processed

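Spleen cells of young and aged parabiotic mice, pairs joined by surgery so that they share a circulation, were profiled by droplet single-cell RNA sequencing with antibody tags (10x Genomics 3′ kit, version 3.1 per the labels). Isochronic pairs held mice of 1 age and heterochronic pairs joined a young to an aged mouse. Young mice were B6.SJL-Ptprca Pepcb/BoyJ, which carry the CD45.1 form of the leukocyte antigen encoded by Ptprc, and aged mice were C57BL/6J, which carry CD45.2. Age and strain are therefore the same split in every comparison between CD45.1 and CD45.2 cells. In the aged heterochronic host, CD45.1 cells came from the young partner and CD45.2 cells were the host's own. There the origin from host or partner is the same split too. The design text gives ages of 4 and 20 months and 28 days of joining, and the surgery protocol gives 3 and 22 months and 4 weeks. Per the labels, live (Hoechst-negative) CD45.1+ or CD45.2+ cells were sorted, 40000 cells per sample, with 4 mice per group pooled into 6 groups, and 25000 cells were loaded per library. The stated depth was 30000 cDNA reads and 3000 antibody tag reads per cell. Each group has 1 library.

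The deposited matrices hold whole-number counts, UMIs per feature and cell, for 32285 genes and 34 antibody tags. Per the file headers they were written by Cell Ranger 7.0.1, whereas the labels name Cell Ranger 7.1 with bcl2fastq, Seurat and the mm10 genome build. The rules for calling cells and for reads that map to several genes are not given in the sources used here. A deposited aggregate matrix of counts joins 6 libraries. The files under the CD45.1 and the CD45.2 label of the young heterochronic mouse were byte for byte the same, with 11145 barcodes. The 6 sample files therefore hold 5 distinct libraries. All 5 were found in the aggregate by their barcodes, and the aggregate held 1 further library, of 11662 barcodes, that no sample file holds. The doubly deposited library entered no comparison that needs its CD45 label, and the further library stayed in no group. Both took part in the clustering, the further library with its aggregate counts, and their values are given in the closing section. Against each library's own matrix, the aggregate held between 89.2% and 100% of the gene UMIs, so the values given for the other libraries come from their own matrices.

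Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept. Doublet scores were computed per library with Scrublet in Scanpy 1.11.5, and the cells with the highest scores were left out, at 0.8% per 1000 barcodes, the share that the load implies. The kept cells of the 6 libraries, 50287 in all, were clustered together without batch integration (Leiden, resolution 1; 2000 variable genes, 30 principal components, 15 neighbours). Receptor gene segments, haemoglobin, sex-linked, mitochondrial, ribosomal and immediate early genes were left out of the clustering. Clusters were named from 20 fixed marker sets where at least 3 markers were detected in the cluster. Cells of the T lineage were clustered again at resolution 1, and CD8 T-like cells once more at resolution 0.6, with the 253 genes of the state markers and gene lists left out. T clusters were called CD8 T-like or CD4 T-like where cells with UMIs of only Cd8a or Cd8b1, or of only Cd4, outnumbered the other kind at least 4-fold. In 4 T clusters that mix both kinds, each cell was assigned by its own Cd4, Cd8a and Cd8b1 UMIs. A regulatory T-like (Treg-like) cluster needed a Foxp3 UMI in at least 20% of its cells. A cluster led by markers of another class was left unnamed, and a CD8 sub-cluster whose top 10 genes held more markers of another state was left unnamed. The assignment by cell, the Foxp3 rule and the rule for unnamed sub-clusters were chosen after the data were seen.

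Raw UMIs were summed over the cells of a class in each library and scaled to the class total as CPM. Ratios carry exact conditional binomial 95% intervals, shares of cells exact Clopper-Pearson 95% intervals, and CPM exact Poisson 95% intervals. All intervals and limits cover counting error only. With 1 library per group there is no replicate, so no test between groups was run and no p-value is given for cells. No paired analysis was possible because each group has 1 library. Genes with at least 100 UMIs over both libraries of a comparison were called measured, and 0.5 UMIs were added to each library for log2 ratios. Where a library held 0 UMIs of a gene, the bound was set against a floor of 3 counts, and the limit for a share of 0 was set at 3 counts of the total. Shares of cells with a UMI of a gene were computed after thinning each cell to 2000 UMIs, and cells below that depth were left out. B-like cells gave the background from free RNA for genes that they lack.

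The 19 gene lists, the marker sets, the comparisons and the rule for naming genes were set before the data were examined. By that rule the text draws on the 12 higher and 12 lower measured genes per comparison in CD8 T-like cells, and 4 and 4 in each other class with at least 100 cells in both libraries, whose interval bound nearest to no difference lay farthest from it. Immunoglobulin genes, T cell receptor segments, haemoglobins, mitochondrial, ribosomal and Y-linked genes, Xist, Tsix and gene models named Gm or Rik were left out of the naming. Members of the lists and the genes fixed for CD8 states may be named besides, and Ptprc and Gzmk are always given. A list's median log2 ratio was set among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Lists for other cell types (B cell, erythroid and myeloid transcripts) were read as a measure of free RNA. Gene positions came from GENCODE M21 (mm10), in which 32158 of the 32285 genes had a position, and genes within 20 Mb of Ptprc were listed apart.

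The alternatives were other cell filters, clustering resolutions and thinning depths, no doublet removal, a gate on single genes, leaving out cells with a B cell UMI, other filters on low counts, a pseudocount of 5, median of ratios scaling, a mean over cells, naive-like and other CD8 T-like cells apart, and the aggregate matrix. A pair of alternatives was added after the data were seen, and the planned comparisons of the young heterochronic libraries were left out because their files are identical. The interval and the list percentile were tested on simulated data made from the isochronic CD8 T-like counts. Intervals held the true ratio for 95.4% of the genes left as they were and for 94% of the genes set 2-fold apart, and 1.5% of 200 random lists fell outside the central 95% of the random lists. The simulation drew Poisson counts per gene for whole libraries, the error that the interval assumes. It could not show how the intervals hold where UMIs gather in few cells. Software was Python 3.11.15, AnnData 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and Matplotlib 3.10.9.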

Results

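The series compared spleen leukocytes of young and aged mice that had shared a circulation by parabiosis. Per the series title its question concerns aged CD8 T cells and Gzmk, which encodes the secreted serine protease granzyme K. Libraries with a usable label came from the young isochronic mouse, the aged isochronic mouse, and the CD45.1 (young) and CD45.2 (aged) cells of the aged heterochronic host. These are called below the young isochronic, aged isochronic, aged-host CD45.1 and aged-host CD45.2 libraries. They held 10646, 8988, 7515 and 9890 barcodes in this order, against 25000 cells stated as loaded and 40000 stated as sorted for each. Their gene UMIs came to 71266630, 66078079, 48420320 and 82232379, and their median UMIs per barcode to 5603.5, 5727, 5528 and 6120.5. After the filters 8796, 7665, 6155 and 8622 cells were kept. The doublet score left out 907, 646, 452 and 782 cells, while the threshold that Scrublet set by itself would have called 3.79%, 2.46%, 2.54% and 3.19% of barcodes. There was 1 library per group, pooled from 4 mice, so values stand without replicates and none of the differences below was tested. A measured difference follows the host in 1 more way: the median CD45 antibody tag count per kept cell was 1034 UMIs in the young isochronic library and 30, 9 and 11 UMIs in the aged isochronic, aged-host CD45.1 and aged-host CD45.2 libraries.

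B-like cells were the largest class of every library, and plasma cells had a higher share in both libraries of aged cells. Plasma cells, which secrete antibody, made up 0.5002% (95% interval 0.364 to 0.671) of the young isochronic and 1.80% (1.52 to 2.12) of the aged isochronic library. In the aged host they made up 0.146% (0.0669 to 0.277) of CD45.1 and 4.27% (3.85 to 4.72) of CD45.2 cells. Natural killer (NK)-like cells, innate killers of infected and tumour cells, made up 4.79% (4.35 to 5.25) of the young isochronic library, 1.04% (0.828 to 1.30) of the aged isochronic, 1.28% (1.02 to 1.597) of the aged-host CD45.1 and 1.44% (1.20 to 1.71) of the aged-host CD45.2 library. CD4 T-like cells were fewer in both libraries of aged cells, at 6.51% (5.97 to 7.09) against 8.63% (8.05 to 9.24) in the isochronic mice and 5.196% (4.74 to 5.69) against 11.1% (10.3 to 11.9) in the aged host. CD8 T-like cells, the cytotoxic lineage, took similar shares of 11.2% (10.6 to 11.9) in the young isochronic, 11.98% (11.3 to 12.7) in the aged isochronic and 11.4% (10.6 to 12.2) in the aged-host CD45.1 library, and 14.96% (14.2 to 15.7) in the aged-host CD45.2 library. Treg-like cells, which restrain immune responses, ranged from 1.85% to 2.78%. Neutrophil-like cells made up 9.16% (8.56 to 9.79) of the aged-host CD45.2 library and between 2.15% and 3.68% of the other 3.

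Several clusters were kept out of the T cell classes. A cluster led by the NK receptor genes Klra1 and Klra7 held 1.36%, 0.561%, 0.666% and 1.44% of the cells of the young isochronic, aged isochronic, aged-host CD45.1 and aged-host CD45.2 libraries. A cluster with Zbtb16 and Cxcr6 held 1.15%, 0.691%, 0.0650% and 1.10% in the same order. A cluster of cycling cells held 0.375%, 0.444%, 0.276% and 0.592%. Cells of mixed clusters that showed neither or both of the CD4 and CD8 transcripts were left unassigned and made up 0.398%, 1.01%, 0.536% and 0.812%.

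**Figure D1:**
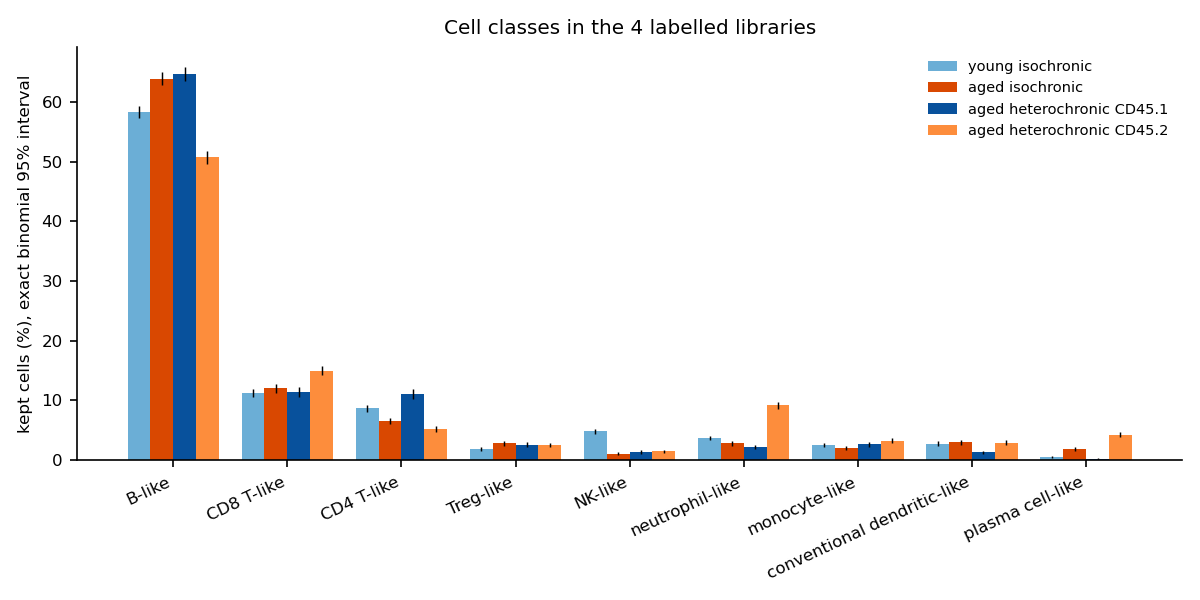
Share of kept cells (percent, vertical axis) in each cell class (horizontal axis) for the 4 labelled libraries, with exact Clopper-Pearson 95% intervals that cover counting error only. Plasma cells reached 4.27% in the aged-host CD45.2 library against 0.146% in the aged-host CD45.1 library.

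Naive-like cells were the main CD8 T-like state in both libraries of young cells and a minority in both libraries of aged cells. They made up 81.0% (78.4 to 83.4) of 985 young isochronic and 24.2% (21.5 to 27.1) of 918 aged isochronic CD8 T-like cells. In the aged host they made up 86.7% (84.0 to 89.1) of 699 CD45.1 and 24.6% (22.3 to 27.0) of 1290 CD45.2 cells. A Gzmk-positive-like sub-cluster, S03, with the chemokine genes Ccl3 and Ccl4 among its leading genes, held 3.55% (2.49 to 4.91), 17.5% (15.1 to 20.2), 2.58% (1.53 to 4.04) and 12.6% (10.9 to 14.6) in the young isochronic, aged isochronic, aged-host CD45.1 and aged-host CD45.2 libraries. The top 10 genes of S03 also held Trgv2 and Tcrg-C2, members of the gamma-delta T marker set, and those of S00, described below, held Cd163l1 of that set. A memory-like sub-cluster, S04, led by Slc35f3 held 18.2% (15.7 to 20.8) of aged isochronic and 15.97% (14.01 to 18.1) of aged-host CD45.2 cells. It held 0 of 985 young isochronic cells, which at 3 counts of the total allows a share of up to 0.305%, and 0 of 699 aged-host CD45.1 cells, which allows up to 0.429%. An unnamed sub-cluster, S05, led by Gm4208 and Spats2 held 10.9% (9.28 to 12.8) of aged-host CD45.2 and 1.09% (0.524 to 1.99) of aged isochronic cells. In the young isochronic library it held 0.102%, and in the aged-host CD45.1 library 0 cells. The largest unnamed sub-cluster, S00, led by the NK receptor genes Klra7 and Klrc1, held 14.4%, 37.8%, 10.0% and 33.6%, and an interferon-like sub-cluster 0.914%, 0.872%, 0.715% and 0.620%. The marker scores of S00 and S05 were highest for the memory state (0.634 and 0.684). Both stayed unnamed because their top 10 genes held a marker of another state and none of memory. The absence of S04 therefore does not mean that the young libraries lacked cells with memory markers. Left without a name, sub-cluster S08 held 0%, 0.327%, 0% and 1.63%.

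**Figure D2:**
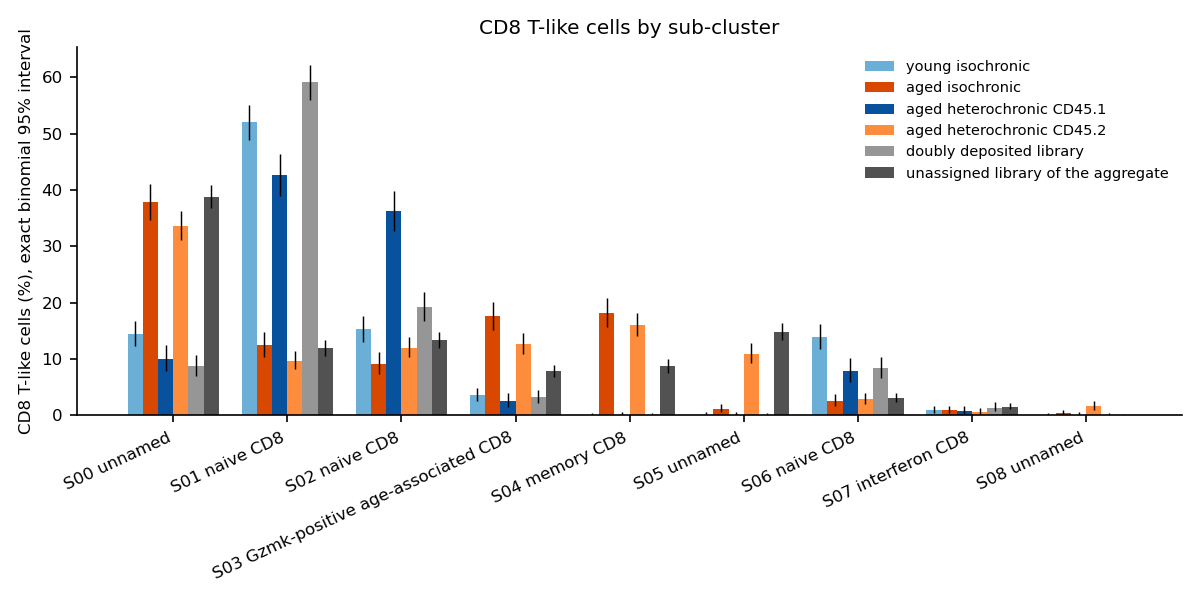
Share of CD8 T-like cells (percent, vertical axis) in each CD8 sub-cluster (horizontal axis) for the 4 labelled libraries, the doubly deposited library and the unassigned library of the aggregate, with exact Clopper-Pearson 95% intervals that cover counting error only. Sub-cluster S04 held 18.2% and 15.97% of cells in the labelled libraries of aged cells and 0 cells in both labelled libraries of young cells.

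Gzmk (ENSMUSG00000042385; mm10 chromosome 13, 113171608 to 113225908) was detected in more CD8 T-like cells of aged than of young origin. After thinning to 2000 UMIs, 11.0% (9.07 to 13.2) of aged isochronic and 1.12% (0.560 to 1.99) of young isochronic cells held a Gzmk UMI. In the aged host the shares were 8.23% (6.79 to 9.87) of CD45.2 and 0.862% (0.317 to 1.87) of CD45.1 cells. Thinning left out 2, 2, 3 and 2 cells of the young isochronic, aged isochronic, aged-host CD45.1 and aged-host CD45.2 libraries, and without it the shares were 1.93%, 15.9%, 1.14% and 13.2%. In B-like cells, which should lack the transcript, the thinned Gzmk share was 0% in both libraries of young cells, 0.0844% in the aged isochronic and 0.0696% in the aged-host CD45.2 library, with 203, 156, 165 and 62 B-like cells left out. Median UMIs were 8572, 10520.5, 9458 and 9053 in CD8 T-like and 4961, 5329, 5244 and 5349 in B-like cells. Most Gzmk-positive cells of aged origin came from a cluster, T14, led by Gzmk, Epha3 and Ccl5 that mixes Cd4 and Cd8 cells. It held 3.67% and 3.15% of all cells in the aged isochronic and aged-host CD45.2 libraries and 0.364% and 0.536% in the young isochronic and aged-host CD45.1 libraries. Without the cells of mixed clusters, an alternative added after the data were seen, the shares of CD8 T-like cells with a Gzmk UMI were 0.111%, 1.24%, 0% and 1.43% in the order young isochronic, aged isochronic, aged-host CD45.1 and aged-host CD45.2. Cells of T14 were called CD8 T-like by their own UMIs, 29 of 32, 151 of 281, 15 of 33 and 146 of 272 in this order, with medians of 9, 7, 12 and 5 Cd8a and Cd8b1 UMIs. In clusters of CD4 T-like cells, 3.56%, 2.13%, 3.11% and 2.36% of cells also held only such UMIs, with medians of 1, 2, 1 and 1, so some CD4 cells without a Cd4 UMI can be among the Gzmk-positive cells counted as CD8.

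Other genes fixed for the CD8 states differed along with the state shares. Ccl5, a chemokine of memory and effector T cells, had a UMI in 77.5% of aged isochronic against 21.6% of young isochronic and in 77.2% of aged-host CD45.2 against 16.8% of aged-host CD45.1 CD8 T-like cells, with 8.36%, 4.31%, 3.37% and 1.70% in B-like cells of the same libraries. Gzmb, which encodes the cytotoxic protease granzyme B, had a UMI in 9.06% of aged isochronic, 1.02% of young isochronic, 5.75% of aged-host CD45.2 and 0.718% of aged-host CD45.1 cells. B-like cells of these 4 libraries had Gzmb in 0%, 0.0812%, 0.0232% and 0%. For Lef1, a transcription factor of naive T cells, the shares ran the other way at 50.6%, 79.2%, 53.2% and 80.0%, with 2.03%, 3.66%, 0.603% and 2.83% in B-like cells. Without thinning these genes had a UMI, in the same order of libraries, in 83.4%, 33.0%, 80.2% and 23.7% (Ccl5), 22.3%, 1.52%, 13.5% and 1.29% (Gzmb), and 85.5%, 96.9%, 88.0% and 97.7% (Lef1) of CD8 T-like cells. For Pdcd1, the PD-1 checkpoint receptor, the thinned shares were 2.62%, 0.916%, 1.24% and 0.431%, against at most 0.0696% in B-like cells, and the unthinned shares 5.01%, 1.52%, 3.64% and 1.00%.

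**Figure D3:**
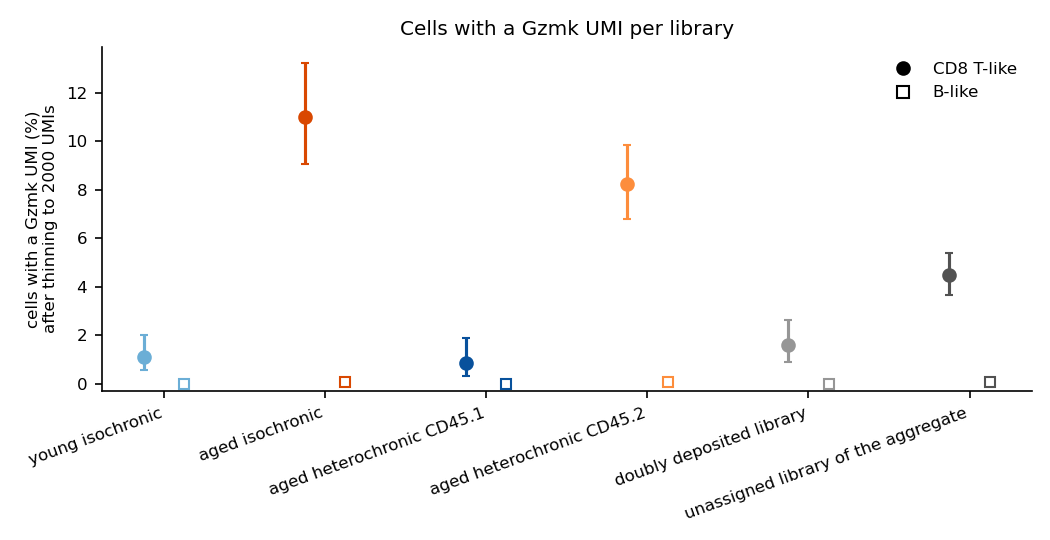
Share of cells with a Gzmk UMI after thinning to 2000 UMIs per cell (percent, vertical axis) in CD8 T-like and B-like cells of each library (horizontal axis), with exact Clopper-Pearson 95% intervals that cover counting error only. The aged isochronic and aged-host CD45.2 libraries reach 11.0% and 8.23% of CD8 T-like cells, against 1.12% and 0.862% in the young isochronic and aged-host CD45.1 libraries.

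The isochronic comparison asked how CD8 T-like cells of aged mice joined to aged partners differ from those of young mice joined to young partners. Age-associated and cytotoxic genes were higher and naive genes lower in the aged library, among 8934 measured genes. Of the age-associated CD8 list, 17 of 18 measured members were at least 1.5-fold higher (median log2 ratio 1.69, percentile 100 among random lists). Gzmk was 6.37-fold higher (95% interval 5.04 to 8.14; 59.0 against 9.26 CPM). Among CD8 T-like cells that are not naive-like, the log2 ratio of Gzmk was 0.81 and the median of the age-associated list 0.59. Ccl5 was 7.19-fold (7.04 to 7.34) higher, the calcium-binding protein gene S100a6 12.9-fold (12.1 to 13.8), and Eomes, a memory T cell transcription factor, 3.35-fold (2.93 to 3.86). Tox, a transcription factor of exhausted T cells, was 1.15-fold lower (1.09 to 1.21). Of the cytotoxic and effector list, 13 of 15 were at least 1.5-fold higher (median 1.98, percentile 100), among them Gzmm at 13.03-fold (11.0 to 15.5), Gzmb at 5.25-fold (4.22 to 6.60), the death ligand gene Fasl at 8.09-fold (6.13 to 10.9) and the egress receptor gene S1pr5 at 26.5-fold (14.2 to 55.8). The central and virtual memory list had 11 of 13 members higher and Itgae lower (median 1.53, percentile 100), including Il2rb, a receptor chain for interleukins 2 and 15, at 2.42-fold (2.25 to 2.61) and Cxcr3 at 3.07-fold (2.71 to 3.49). Itgae, an integrin of tissue-resident cells, was 2.96-fold lower (2.46 to 3.58). Of the naive CD8 list, 7 of 15 were at least 1.5-fold lower and 0 higher (median −0.48, percentile 0), with Ccr9, a gut-homing chemokine receptor, 4.86-fold lower (3.98 to 5.97), Lef1 2.02-fold lower (1.95 to 2.09) and Ccr7, the lymph node homing receptor, 1.94-fold lower (1.79 to 2.11). Il7r, the receptor for the survival cytokine interleukin 7, was 1.43-fold higher (1.39 to 1.48).

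By the naming rule the leading higher genes also held Slc35f3 (529 against 3 UMIs, 159-fold, 54.1 to 773), the inhibitory receptor gene Fcgr2b (55.8-fold, 31.0 to 112), Ccr2 (12.6-fold, 10.0 to 16.1), Anxa1 (24.5-fold, 10.2 to 76.7), Fgl2 (19.01-fold), Eml6 (15.5-fold), Klrb1c (16.2-fold) and Epha3 (14.6-fold). Lhfp had 173 UMIs against 0, at least 51.9-fold. Slc35f3, Klrb1c, Fcgr2b, Ccr2 and Gzmm are among the genes that lead sub-cluster S04, Lhfp is among those of S05 and Gzmk and Epha3 among those of S03. Of 50 aged isochronic S04 cells with a UMI of a T cell receptor beta segment (Trbv), 88% held Trbv12-2. A clone may therefore account for S04 there, a reading made after the results were seen. How far it carries these ratios was not tested. Without sub-clusters S04, S05 and S08, Lhfp still had 58 against 0 UMIs. The leading lower genes were Mtss1 (5.66-fold, 4.27 to 7.62), Plaur (5.60-fold, 4.01 to 8.002), Atp1b1 (4.62-fold, 3.61 to 5.98), Id3, a regulator of lymphocyte differentiation (4.21-fold, 3.48 to 5.13), Dapl1 (3.32-fold, 3.11 to 3.54), Actn1 (3.77-fold), Cxxc5 (4.80-fold), Gria3 (4.98-fold), Trnp1 (4.49-fold), Auts2 (3.84-fold) and Rgcc (3.601-fold). Within naive-like cells alone the age-associated, cytotoxic and memory lists were not higher (medians −0.069, −0.019 and −0.14), Ccr2 was lower (log2 ratio −0.21) and Dapl1 was not lower (0.012), while Gzmk was higher (3.30) on 7 against 2 UMIs.

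Metabolic lists leaned higher in the aged isochronic CD8 T-like cells with small medians. Glycolysis had 0 of 13 members at least 1.5-fold apart (median 0.35, percentile 100) and mitochondrial respiration 1 of 16 higher (median 0.20, percentile 99.7). Medians of the exhaustion and checkpoint list (0.09), proliferation (0.18), MHC class I (0.09), cell stress and unfolded protein (0.08) and follicular and exhausted CD4 (0.09) were above 0, and those of interferon response (−0.09), MHC class II (−0.15) and senescence and cell cycle inhibitors (−0.09) below 0, all between percentiles 13.7 and 93.7. The immediate early list, which responds within minutes to stimulation or handling, had a median of −0.20 (percentile 1.78), with Fos 2.15-fold lower (1.68 to 2.78) and Egr1 2.42-fold lower (1.80 to 3.27). In the age-associated B list, 4 of 7 measured members were higher (median 0.86, percentile 100), among them Tbx21 and Cxcr3, which the memory list also holds. This age-associated B median was below 0 under a single-gene gate (−0.24), without doublet removal (−0.0072) and in naive-like cells alone (−0.059). Marker lists of other cells had medians of −0.07 (B cell free RNA) and −0.45 (erythroid, 4 measured), while Igkc, which encodes an antibody light chain, was 2.87-fold higher (2.69 to 3.07).

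The aged host held aged CD45.2 and young CD45.1 cells in the same circulation, and this comparison asked how far their CD8 T-like cells differ there. Age-associated, cytotoxic and memory genes were higher and naive genes lower in CD45.2 cells, among 8898 measured genes. Gzmk was 12.8-fold higher in CD45.2 cells (8.65 to 19.8; 49.2 against 3.84 CPM), and 15 of 16 measured age-associated CD8 genes were at least 1.5-fold higher (median 1.89, percentile 100). Among CD8 T-like cells that are not naive-like, the log2 ratio of Gzmk was 1.26 and the list median 0.79, and in naive-like cells alone the list median was 0.11 and that of the cytotoxic list below 0 (−0.10). S100a6 was 18.2-fold (16.6 to 20.0), Ccl5 9.64-fold (9.40 to 9.89) and Eomes 4.60-fold (3.85 to 5.53) higher, and Tox 1.05-fold lower (0.994 to 1.11). Of the cytotoxic and effector list 14 of 15 were higher (median 2.72, percentile 100), with Gzmm at 25.3-fold (19.4 to 33.5), Gzmb at 11.0-fold (7.11 to 17.99), Fasl at 27.0-fold (15.7 to 50.9) and the NK receptor gene Klre1 at 23.7-fold (16.2 to 36.1). Of the memory list 11 of 13 were higher (median 1.84, percentile 100), with Cd44, an adhesion receptor of antigen-experienced cells, at 4.12-fold (3.56 to 4.81). Of the naive list 7 of 15 were at least 1.5-fold lower (median −0.52, percentile 0), with Ccr9 7.001-fold (5.56 to 8.88), Igfbp4 5.26-fold (4.66 to 5.95) and Ccr7 2.04-fold (1.86 to 2.23) lower, and Il7r was 1.72-fold higher (1.66 to 1.78).

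Other leading genes in the aged host were Slc35f3 (669 against 1 UMIs, 381-fold, 68.2 to 15080), Epha3 (63.1-fold, 21.4 to 307), Fcgr2b (49.3-fold, 25.8 to 108), Fgl2 (47.9-fold), Eml6 (40.5-fold), Olfm1 (146 against 1 UMIs, 83.2-fold, 14.7 to 3308), Lhfp (113 against 0 UMIs, at least 21.5-fold) and Klra8 (108 against 0 UMIs, at least 20.5-fold). Lower were Plaur (6.71-fold, 4.83 to 9.50), Atp1b1 (6.06-fold, 4.65 to 7.97), Gria3 (6.69-fold), Ramp1 (4.99-fold), Kcnmb4 (5.23-fold), Mtss1 (4.24-fold), Slc16a10 (4.83-fold), Cxxc5 (4.24-fold), Actn2 (3.90-fold) and Dapl1 (3.26-fold). Among cells that are not naive-like, Slc16a10 was higher instead (log2 ratio 0.17). As in the isochronic comparison, Slc35f3, Fcgr2b and Gzmm are among the genes that lead sub-cluster S04, Epha3 among those of S03 and Lhfp among those of S05. The MHC class II list, which serves antigen presentation, had a median of −0.41 (percentile 0.160) but 0.49 under a single-gene gate, interferon response −0.19 (percentile 0.280) with Ifi27l2a 2.76-fold lower (2.53 to 3.02), and the age-associated B list 1.42 (percentile 100). Medians of the exhaustion (−0.05), immediate early (0.08), proliferation (0.22, and −0.13 in naive-like cells alone), MHC class I (0.02), mitochondrial respiration (0.08), glycolysis (−0.08), senescence (−0.11), follicular and exhausted CD4 (0.07) and cell stress (0.11) lists lay between percentiles 13.1 and 93.5. Transcripts of other cells also differed between these libraries. All 6 measured myeloid markers were higher in the CD8 T-like cells of the aged-host CD45.2 library (median 2.83, percentile 100; S100a8 11.0-fold, 7.84 to 15.8), in which neutrophil-like cells were 9.16% against 2.15%. Igkc was 11.5-fold higher (10.5 to 12.6) where plasma cells were 4.27% against 0.146%, while the B cell list had a median of −0.32. The erythroid gene Hbb-bs had 0 UMIs in aged-host CD45.1 and 313 in aged-host CD45.2 CD8 T-like cells, at least 59.4-fold higher.

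**Figure D4:**
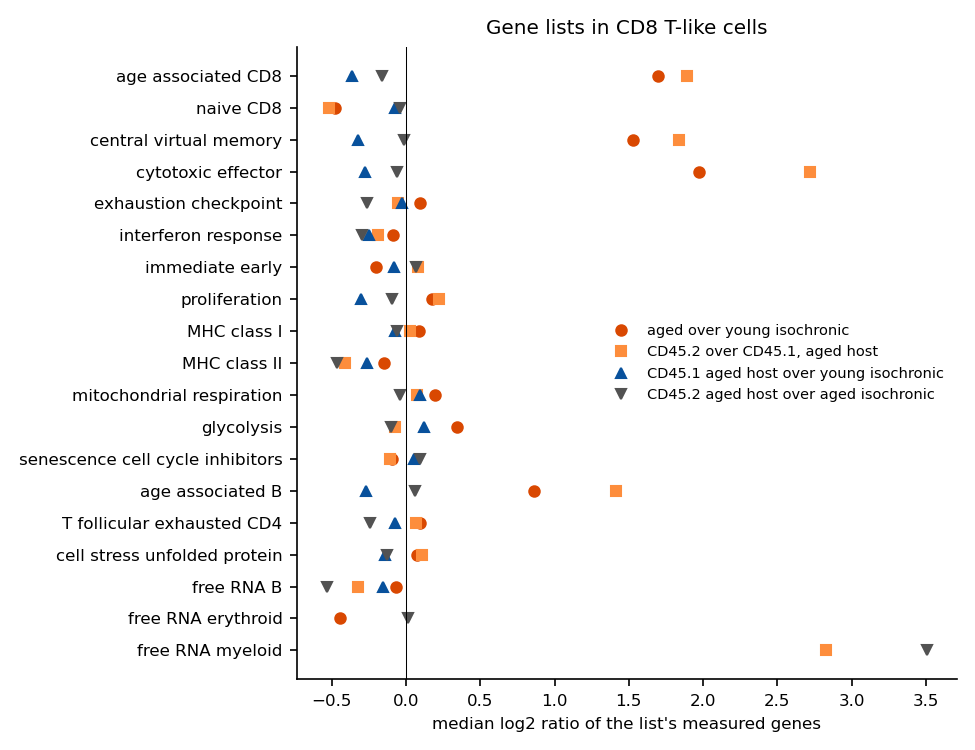
Median log2 ratio of the measured members of each fixed gene list in CD8 T-like cells (horizontal axis) for the 4 comparisons, 1 point per list and comparison. The age-associated CD8 list stands at 1.69 and 1.89 in the age comparisons and at −0.36 and −0.16 in the host comparisons.

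The age comparisons share no library, and their log2 ratios in CD8 T-like cells went together across genes. The genes left out of the naming were left out here too. Over the 8210 other genes measured in both, 69.3% had the same sign, with Pearson r of 0.840 and Spearman rho of 0.586 across genes, which are not independent replicates. Of 300 genes at least 2-fold apart in both, 299 had the same sign. Among the leading named genes, 8 higher (Fcgr2b, Lhfp, S100a6, Fgl2, Slc35f3, Gzmm, Eml6 and Epha3) and 7 lower (Atp1b1, Dapl1, Plaur, Ccr9, Mtss1, Cxxc5 and Gria3) were named in both comparisons. Age and strain differ together in both, and in the aged host the origin from host or partner differs with them. The make-up by state differs too. Naive-like cells were 24.2% of aged against 81.0% of young isochronic and 24.6% of CD45.2 against 86.7% of CD45.1 aged-host cells. In naive-like cells alone the age-associated CD8 medians were −0.069 and 0.11. Whether the ratios go together within a state was not tested. Ptprc (ENSMUSG00000026395; mm10 chromosome 1, 138062861 to 138175708), the gene whose alleles mark the strains, stood at 1525 CPM (1500.0 to 1551) in young isochronic, 1638 (1613 to 1664) in aged isochronic, 1417 (1389 to 1445) in aged-host CD45.1 and 1585 (1562 to 1607) in aged-host CD45.2 CD8 T-like cells. Near it, Tmem37 was 9.43-fold and 6.96-fold higher in aged cells in the isochronic and the aged-host comparison, Tmem163 3.41-fold and 6.32-fold, and Rgs1, a regulator of chemokine receptor signals, 3.11-fold and 3.03-fold. Lower in both, among others, were Stx6 (1.47-fold and 2.00-fold), Ctse (1.37-fold and 1.82-fold) and Csrp1 (1.597-fold and 1.735-fold). Of 100 and 101 measured genes near Ptprc, without those left out of the naming, 10 and 12 were at least 1.5-fold higher and 5 and 3 lower in aged cells. The share of all measured genes this far apart was not counted, so these numbers cannot show an excess near Ptprc. Tmem37 is also among the genes that lead sub-cluster S05.

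**Figure D5:**
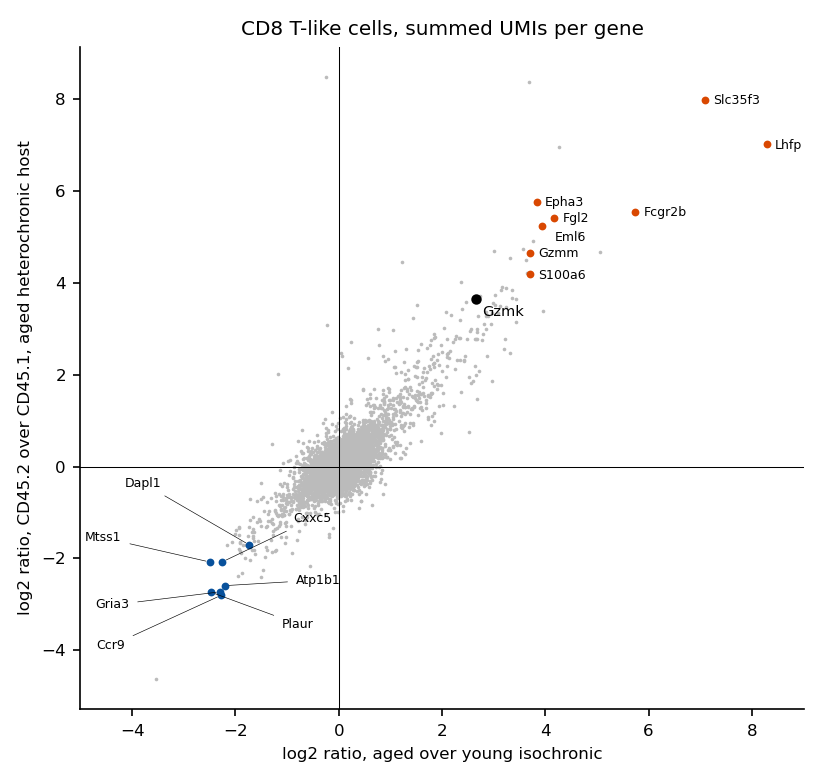
Log2 ratio of each gene measured in both comparisons in CD8 T-like cells, aged over young isochronic (horizontal axis) against CD45.2 over CD45.1 in the aged host (vertical axis), 1 point per gene. The points include the genes left out of the naming. Without those, 69.3% of 8210 genes have the same sign on both axes, and Gzmk stands at 2.66 and 3.65.

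Young CD45.1 cells from the aged host were set against those of young isochronic mice to ask what an aged partner's circulation goes with in young cells. Those of the aged host came from its partner, while the young isochronic library also holds the host's own cells, so cell origin differs too. In CD8 T-like cells, age-associated CD8 genes were not higher in the young cells of the aged host but lower, in 4 of 15 measured members by at least 1.5-fold (median −0.36, percentile 0). In naive-like cells alone, which were 86.7% against 81.0% of the CD8 T-like cells, this median was −0.090. Gzmk was 2.41-fold lower (1.53 to 3.90) on 26 UMIs in 8 cells against 81 UMIs in 19 cells, and the intervals of the thinned shares of cells, 0.862% (0.317 to 1.87) and 1.12% (0.560 to 1.99), overlap. Gzmk in CD4 T-like cells went the other way. It stood at 14.4 CPM (11.3 to 18.1; 73 UMIs) in the aged-host CD45.1 and 0.959 (0.311 to 2.24; 5 UMIs) in the young isochronic library. Cluster T14 held 9 against 1 cells with only Cd4 UMIs, of which 8 against 0 had a Gzmk UMI. Among CD8 T-like cells, S100a4 was 2.10-fold (1.66 to 2.69) and S100a6 1.602-fold (1.43 to 1.79) lower. Of the cytotoxic and effector list 5 of 13 were lower (median −0.27, percentile 0.540, and 0.044 in naive-like cells alone), with the granzyme genes Gzma 9.16-fold (5.80 to 15.3) and Gzmb 3.50-fold (2.16 to 5.91) lower. Without cells with a B cell UMI, Gzmb was higher instead (log2 ratio 1.16; 18 against 10 UMIs). Few cells held Gzma, 0.718% (0.234 to 1.67) against 1.22% (0.632 to 2.12) after thinning and 2.00% against 3.86% without it. In B-like cells Gzma stood at 1.74 against 7.06 CPM, and NK-like cells were 1.28% against 4.79% of these libraries. Lyz2, a member of the myeloid list that was read as a measure of free RNA, was 5.46-fold lower (3.22 to 9.88). Among genes outside the lists, the lower ones included Lgals3 (2.94-fold), Disc1 (2.36-fold), Sytl2 (2.24-fold), Neto2 (2.54-fold), Rad51b (2.23-fold) and Slc9a7 (1.88-fold).

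Higher in the young cells of the aged host was Xcl1, a chemokine that attracts cross-presenting dendritic cells, at 2.86-fold (2.40 to 3.42). Xcl1 was lower instead without the cells of mixed clusters (log2 ratio −0.68) and under a single-gene gate (−0.51). Other higher genes were Socs3, a feedback inhibitor of cytokine signals, at 2.56-fold (2.14 to 3.07), Bcl3 at 2.48-fold (1.87 to 3.33), Trnp1 at 2.35-fold (1.94 to 2.85), Neb at 3.49-fold (2.32 to 5.37), Cd163l1 at 3.33-fold, Matk at 2.11-fold and Prelid2 at 1.98-fold. Among cells that are not naive-like, Xcl1 (log2 ratio −0.16), Neb (−1.44) and Prelid2 (−0.19) were lower instead. Trnp1 is among the genes that lead sub-cluster S02, which held 36.2% (32.6 to 39.9) of aged-host CD45.1 and 15.2% (13.04 to 17.6) of young isochronic CD8 T-like cells. The memory list had a median of −0.32 (percentile 0.0100), interferon response −0.25 (percentile 0.2, and 0.09 in cells that are not naive-like) with Ifit1 1.83-fold lower (1.34 to 2.52), proliferation −0.30 (percentile 1.06) with Stmn1 2.03-fold lower (1.51 to 2.75), and the age-associated B list −0.27 (percentile 1.24). Mitochondrial respiration and glycolysis had medians of 0.10 and 0.12 (both percentile 100), with 0 members at least 1.5-fold apart. Medians of the naive list (−0.07), exhaustion (−0.03), immediate early (−0.08), MHC class I (−0.07), MHC class II (−0.26), senescence (0.06), follicular and exhausted CD4 (−0.07), cell stress (−0.14) and B cell free RNA (−0.16) lists lay between percentiles 2.31 and 91.2. Hbb-bs had 0 against 277 UMIs, at least 71.4-fold lower. Under median of ratios scaling the log2 ratio of the scaling totals shifted by −0.07, which raised all log2 ratios of this comparison by as much. The shift was smaller in the other comparisons.

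Aged CD45.2 cells from the aged host joined to a young partner were set against those of aged isochronic mice to ask what a young partner goes with in aged cells. Those of the aged host were its own, while the aged isochronic library also holds the partner's cells, so cell origin differs too. The interferon response, MHC class II and age-associated CD8 lists had medians below 0, among 9204 measured genes. Ifi27l2a was 2.33-fold (2.14 to 2.54) and the interferon-induced GTPase gene Iigp1 2.03-fold (1.62 to 2.56) lower, and the interferon response list had a median of −0.30 (percentile 0). MHC class II had 2 of 7 members lower (median −0.46, percentile 0), and the B cell list 4 of 8 lower (median −0.53, percentile 0), with Cd74 in both lists, where B-like cells were 50.7% against 63.9% of the libraries. With genes of at least 500 UMIs the B cell list was above 0 instead (3 members, median 0.43). For Gzmk the ratio was 1.20-fold lower (1.07 to 1.35; 49.2 against 59.0 CPM), and without the cells of mixed clusters it was higher instead (log2 ratio 0.80). Of the age-associated CD8 list 1 of 19 was at least 1.5-fold lower, Ccl3 at 2.44-fold (1.86 to 3.23), and 1 higher, the receptor gene Cd160 at 1.597-fold (1.42 to 1.79; median −0.16, percentile 0.05). Ccl3 too was higher without the mixed clusters (log2 ratio 1.04) and in naive-like cells alone (3.09, on 15 against 1 UMIs). Gzmb was 1.67-fold (1.46 to 1.90) and Gzma 1.62-fold (1.36 to 1.92) lower, the 2 of 16 cytotoxic genes past 1.5-fold (median −0.06).

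Other lower genes were Penk, which encodes proenkephalin (5.32-fold, 3.24 to 9.13), Vmn2r96 (2.87-fold, 2.38 to 3.48), Ptger3, a prostaglandin E2 receptor (2.90-fold, 1.99 to 4.31), Nrp1 (2.17-fold), Gvin1 (1.78-fold), Hotairm1 (2.14-fold), Nacc2 (2.21-fold), Styk1 (2.04-fold) and Glis3 (2.29-fold). Higher were Fkbp5, a gene induced by glucocorticoids (2.29-fold, 2.05 to 2.56), Xcl1 (1.78-fold, 1.63 to 1.95), Trnp1 (3.25-fold, 2.31 to 4.68), Fos (2.05-fold, 1.62 to 2.62), the heat shock gene Hspa1a (101 against 1 UMIs, 82.7-fold, 14.5 to 3296) and Spats2 (2.04-fold), which leads sub-cluster S05 and was lower instead without sub-clusters S04, S05 and S08 (log2 ratio −1.22) and in naive-like cells alone (−0.73, on 5 against 7 UMIs). Hotairm1 was not lower in naive-like cells alone (0.019). The other leading genes were neutrophil transcripts, S100a8 (12.6-fold, 9.32 to 17.4), S100a9 (11.4-fold, 8.96 to 14.8), Camp (12.02-fold), Lcn2 (15.6-fold), Ngp (10.4-fold) and Slpi (4.09-fold), with 5 of 5 measured myeloid markers higher (median 3.51, percentile 100) where neutrophil-like cells were 9.16% against 2.77%. Exhaustion (−0.26, percentile 0.445), follicular and exhausted CD4 (−0.24, percentile 0.430), cell stress (−0.13, percentile 1.66) and glycolysis (−0.10, percentile 6.55) had medians below 0. Immediate early genes (0.07, percentile 98.7), senescence (0.09, percentile 97.3) and the age-associated B list (0.06, percentile 93.5) had medians above 0. Medians of the naive (−0.04), memory (−0.01), proliferation (−0.09), MHC class I (−0.06), mitochondrial (−0.04) and erythroid (0.01) lists lay between percentiles 22.2 and 72.2.

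CD4 T-like cells had a higher Gzmk CPM than CD8 T-like cells in both libraries of aged cells and in the aged-host CD45.1 library. In the young isochronic library it was lower. In CD8 T-like cells Gzmk stood at 3.84 CPM (2.51 to 5.63) in the aged-host CD45.1 and 9.26 (7.35 to 11.5) in the young isochronic library. Gzmk stood at 135 CPM (123 to 148) in aged isochronic against 0.959 (0.311 to 2.24) in young isochronic CD4 T-like cells, 141-fold higher (59.8 to 435). In the aged host it stood at 130.3 (117 to 145) in CD45.2 and 14.4 (11.3 to 18.1) in CD45.1 cells. These CD4 T-like cells include those assigned one by one from the mixed cluster T14. The chemokine genes Ccl4 (107-fold, 53.9 to 249) and Ccl3 (133-fold, 51.6 to 492) were higher with Gzmk in the aged isochronic CD4 T-like cells, and all 13 measured members of the follicular and exhausted CD4 list were at least 1.5-fold higher (median 1.495, percentile 100). The make-up of the class differed too, with 506 of 759 young against 72 of 499 aged isochronic CD4 T-like cells in cluster T05, 27 against 129 in T04 and 98 against 147 in T08. Pid1 (5.68-fold, 3.04 to 11.8) and Plaur (3.42-fold, 2.35 to 5.12) were lower. In the aged host, Epha3 (67.3-fold, 25.7 to 250) and Ccl4 (66.8-fold, 25.5 to 249) were higher in CD45.2 CD4 T-like cells, where T05 held 54 CD45.2 against 339 CD45.1 cells. Against aged isochronic cells, CD4 T-like cells of the aged-host CD45.2 library had Ccl3 13.4-fold (8.56 to 22.3) and the checkpoint receptor gene Lag3 2.54-fold (1.85 to 3.53) lower. Among Treg-like cells, the decoy receptor gene Il1r2 (13.3-fold, 6.25 to 34) and Gpm6b (6.07-fold, 4.31 to 8.78) were higher and Ly6c1 (8.54-fold, 4.66 to 17.1) lower in the aged isochronic library.

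B-like cells of aged origin had more Bmpr1a, which encodes a receptor for bone morphogenetic proteins, and more of the age-associated B cell genes. Bmpr1a was 7.97-fold (5.10 to 13.04) higher in the aged isochronic library and 19.9-fold (10.6 to 42.1) higher in CD45.2 than in CD45.1 cells of the aged host, and Fgl2 (6.72-fold) and Dnm3 (6.30-fold, 5.13 to 7.82) were higher in the aged isochronic library. Clusters c08, c25 and c04 held 130, 128 and 987 young against 417, 293 and 654 aged isochronic B-like cells. Of the age-associated B list, 6 of 12 measured members were at least 1.5-fold higher in the isochronic comparison (median 0.63) and 9 of 12 in the aged host (median 1.07, percentile 100). Lower in the aged isochronic B-like cells was Pla2g4a (5.77-fold), which lies near Ptprc, and lower in the CD45.2 B-like cells of the aged host were Cecr2 (4.28-fold), Lef1 (4.69-fold) and Sox4 (4.55-fold). Between these libraries the make-up of the B-like class differed too, with 567 CD45.1 and 147 CD45.2 cells in cluster c04 and 84 and 370 in c25. The interferon-induced chemokine gene Cxcl10 was 48.6-fold lower (13.2 to 406; 2 against 124 UMIs) in B-like cells of the aged-host CD45.1 than of the young isochronic library, with 317 and 130 of them in c08. Monocyte-like cells had higher MHC class II in the aged isochronic library (5 of 7 measured members, median 0.68; H2-Eb1 1.93-fold, 1.74 to 2.14), in CD45.2 cells of the aged host (7 of 7, median 1.15), and lower MHC class II in the aged-host CD45.1 than in the young isochronic library (7 of 7, median −1.18). The class joins clusters c01 and c18, which held 165 and 58 cells in the young isochronic, 96 and 60 in the aged isochronic, 35 and 126 in the aged-host CD45.1 and 187 and 93 in the aged-host CD45.2 library. Fkbp5, a gene induced by glucocorticoids, was 5.61-fold (4.06 to 7.94) lower in monocyte-like, 4.81-fold (3.46 to 6.82) in conventional dendritic-like and 2.90-fold (2.22 to 3.84) in neutrophil-like cells of the aged isochronic library. Neutrophil-like cells of the aged-host CD45.2 library had 17.2-fold (14.1 to 21.2) more Elane, an elastase gene of neutrophil precursors, than those of the aged isochronic library, with 15 of 17 proliferation genes higher (median 1.09), where cluster c28 held 358 of 790 against 23 of 212 neutrophil-like cells. Conventional dendritic-like cells of the aged isochronic library had 4.13-fold (2.99 to 5.82) more Il12b, a subunit of the T cell stimulating cytokines interleukins 12 and 23, and 7.09-fold (4.42 to 11.95) less Clec10a.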

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

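Of the tests in this part, those of a single clone in sub-cluster S04 and in sub-cluster S05 and that of a batch marked by the CD45 antibody tag were chosen after the results were seen. B-like cells had a higher share in aged than in young isochronic cells, 63.9% against 58.3%, and a lower share in CD45.2 than in CD45.1 cells of the aged host, 50.7% against 64.7%. For neutrophil-like cells the directions were the other way round, 2.77% against 3.68% in the isochronic mice and 9.16% against 2.15% in the aged host. These opposite directions drew attention, and the difference between the comparisons was not tested. The library of the aggregate that no sample file holds entered no comparison. Its median CD45 antibody tag count was 1982 UMIs per kept cell, against 1034 in the young isochronic library. Of its CD8 T-like cells, 4.47% (3.65 to 5.41) held a Gzmk UMI after thinning, 8.71% (7.58 to 9.96) lay in sub-cluster S04 and 14.9% (13.4 to 16.4) in sub-cluster S05.

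Gzmk was detected in more CD8 T-like cells of CD45.2 than of CD45.1 libraries. The tables argue against depth as the cause, since the thinned share in aged isochronic cells was 9.86 times that in young isochronic cells. Free RNA is argued against too, because the share in B-like cells was at most 0.846% of that in CD8 T-like cells in the CD45.2 libraries. Within the aged host a batch marked by the CD45 antibody tag is argued against, since median tag counts were 11 and 9 UMIs and the Gzmk share still differed 9.55-fold. Between the isochronic libraries the tag count differed along with age and strain, so such a batch cannot be told apart there. Age and strain, and in the aged host the origin from host or partner, stay open as untested biological explanations that the design does not separate. A link with age is a hypothesis found and tested on the same data.

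CD8 T clusters T18 and T19, which overlap memory-like sub-cluster S04 (531 cells) and unnamed sub-cluster S05 (453 cells), held 163 and 9 aged isochronic, 205 and 136 aged-host CD45.2 and 193 and 321 cells of the unassigned library, which is in no group, against 1 cell in the labelled CD45.1 libraries together. Doublets are argued against, with median doublet scores at percentiles 42.1 and 37.7 of all CD8 T-like cells. A T cell clone may account for S05, in which Trbv13-2, a T cell receptor beta segment, held 75.8% of 120 cells with a Trbv UMI (80 of them from the unassigned library, and 85.7% of 35 in the aged-host CD45.2 library), against 11.3% for the commonest segment in naive-like cells. For the planned test on both clusters together the lower share was 25.5% and for S04 alone 25.3% of 225 cells. These shares pool the libraries, so they cannot show clones that differ between libraries. The commonest segment of S04 was Trbv12-2 in the aged isochronic library (88% of 50 cells), Trbv1 in the aged-host CD45.2 library (37.8% of 90 cells) and Trbv26 in the unassigned library (38.8% of 85 cells). In naive-like cells of the aged isochronic library the commonest segment held 12.5%. A clone may therefore account for S04 in that library, a reading made after the results were seen, and the other libraries stay open. Age and strain, and in the aged host the origin from host or partner, stay open, untested.

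The deposit holds 1 library under both young heterochronic labels and 1 library of the aggregate that matches no sample file. Candidate explanations are that the doubly deposited library holds CD45.1 (young) cells and that the unmatched aggregate library holds CD45.2 (aged) cells. Of 3 genes within 20 Mb of Ptprc that differed between CD45.1 and CD45.2 B-like cells in both labelled pairs (Rgs18, Pla2g4a and A230059L01Rik), 100% lay nearer to the CD45.1 level in the doubly deposited library and 100% nearer to the CD45.2 level in the unmatched library. Of 28 such genes elsewhere in the genome, which the prediction did not cover, 26 lay nearer to the CD45.1 level in the doubly deposited library and 27 nearer to the CD45.2 level in the unmatched library, so these values agree in direction with those of the 3 genes. Neither library was moved into a group, since the labels do not settle the CD45 form of either.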

How the results depend on the processing

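The alternatives without mixed T clusters and without sub-clusters nearly absent from CD45.1 libraries were chosen after the data were seen. Of 226 values of the comparisons' main results under alternatives, 162 stayed within the counting interval, 61 moved and 3 reversed; of 1949 others these counts were 1593, 331 and 25. Young cells and aged cells stand for the host comparisons of CD45.1 and CD45.2 cells, and values without a unit are log2 ratios in CD8 T-like cells. Gzmk was higher in aged isochronic cells in each alternative that gave a value (log2 ratio 0.81 to 3.76), as in CD45.2 cells of the aged host (1.26 to 4.35). In the aggregate matrix the aged isochronic, aged-host CD45.1, aged-host CD45.2 and doubly deposited libraries held 89.2%, 93.4%, 97.55% and 93.3% of their own gene UMIs. The stricter cell filter gave CD8 T-like shares of 13.03% (young isochronic), 13.4% (aged isochronic), 13.2% and 16.1% (aged-host CD45.1 and CD45.2). The single-gene gate gave 10.9% (aged isochronic), naive-like shares of 75.6% (young isochronic) and 83.2% (aged-host CD45.1), an age-associated CD8 median of 1.45 (isochronic), and reversed the age-associated B list (isochronic, −0.24), MHC class II (aged host, 0.49) and Xcl1 (young cells, −0.51). Gzmk shares in aged isochronic and aged-host CD45.2 cells were 7.63% and 5.89% at 1000 UMIs and 15.9% and 13.2% without thinning, and 13.6% in aged isochronic cells at 3000 UMIs, which follows from depth. Without cells with a B cell UMI, Gzmk shares were 0.425% (young isochronic) and 0.197% (aged-host CD45.1), Gzmk log2 ratios 3.76 (isochronic) and 4.35 (aged host), and Gzmb reversed in young cells (1.16). With no doublet removal, naive-like shares were 69.6%, 21.2% and 77.2% (young isochronic, aged isochronic, aged-host CD45.1), and the age-associated B list reversed (isochronic, −0.00717). Without sub-clusters nearly absent from CD45.1 libraries, naive-like shares were 30.1% and 34.4% (aged isochronic, aged-host CD45.2), the Gzmk share 11.6% (aged-host CD45.2), Gzmk 3.06 and the age-associated CD8 list 1.48 (isochronic), and Spats2 reversed in aged cells (−1.22). Without cells of mixed T clusters, Gzmk shares were 0.111%, 1.24%, 0% and 1.43% (young isochronic, aged isochronic, aged-host CD45.1, aged-host CD45.2), since these clusters hold most Gzmk-positive cells. Naive-like shares were then 83.4% (young isochronic) and 27.6% (aged-host CD45.2), isochronic values 3.31 (Gzmk), 1.93 (age-associated CD8) and −0.42 (naive CD8), and Xcl1 (young cells, −0.68), Gzmk (aged cells, 0.80) and Ccl3 (aged cells, 1.04) reversed. In naive-like cells only, isochronic values were 3.30 (Gzmk) and −0.023 (naive CD8), and Ccr2 (−0.21), Dapl1 (0.012), age-associated CD8 (−0.069), memory (−0.14), cytotoxic (−0.019) and age-associated B (−0.059) reversed. In the aged host, naive-like cells gave 0.11 (age-associated CD8) and −0.073 (naive CD8), with cytotoxic (−0.10) and proliferation (−0.13) reversed; young cells gave −0.090 (age-associated CD8), with cytotoxic reversed (0.044); and aged cells −4.18 (Gzmk, 0 against 7 UMIs, so the size is set by the added 0.5 UMIs), with Spats2 (−0.73), Ccl3 (3.09) and Hotairm1 (0.019) reversed. In other CD8 T-like cells only, Gzmk, age-associated CD8 and naive CD8 were 0.81, 0.59 and −0.29 (isochronic) and 1.26, 0.79 and −0.30 (aged host). There Slc16a10 (aged host, 0.17) and, in young cells, Xcl1 (−0.16), Neb (−1.44), Prelid2 (−0.19) and interferon response (0.090) reversed, and naive CD8 was 0.057 in aged cells. By mean over cells Gzmk was 3.35 (isochronic) and −0.49 (aged cells). At 20 UMIs or more the age-associated CD8 list was 1.67 (aged host) and −0.47 (young cells), as without a filter on low counts (1.67 and −0.47), and Pearson r 0.796. At 500 UMIs or more naive CD8 was −0.44 (aged host), B cell free RNA reversed (aged cells, 0.43), Pearson r was 0.883 and 72.5% of genes had the same sign, with other genes measured. Median of ratios scaling reversed naive CD8 in young cells (0.000197). Where no construction is named, the cause was not tested. Too few UMIs or members left 40 values out, among them Gzmk in naive-like cells of the aged host. The planned comparisons of the young heterochronic libraries were not run.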

Other observations

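None of the values in this part was tested against another group. In the doubly deposited library, CD8 T-like cells were mostly naive-like (86.7%) and 1.59% (0.895 to 2.62) held a UMI of Gzmk, the transcript of the protease granzyme K, after thinning, which left out 5 cells, and 2.11% without thinning. In the unassigned library of the aggregate 28.3% were naive-like, and Gzmk was found in 7.55% without thinning, while thinning left out 10 cells. Median UMIs of CD8 T-like cells were 9268 and 9100 and of B-like cells 5401 and 5296 in these libraries, and the thinned Gzmk share in B-like cells was 0% and 0.0596%. Gzmk stood at 12.2 and 27.5 CPM in their CD8 T-like cells and at 8.98 and 89.9 CPM in their CD4 T-like cells, and Ptprc at 1610 and 1649 CPM in their CD8 T-like cells. Ccl5, a chemokine of memory and effector cells, was detected after thinning in 15.9% and 73.5%. CD8 T-like cells made up 10.55% and 22.1%, CD4 T-like cells 12.2% and 6.64%, and plasma cells 0.613% and 1.42% of these libraries, which held 11145 and 11662 barcodes with 79125172 and 87391717 gene UMIs.

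Antibody tags were counted in few of the 34 channels. The T cell receptor beta chain tag had medians of 180, 218.5, 346 and 175.5 UMIs in CD8 T-like cells of the young isochronic, aged isochronic, aged-host CD45.1 and aged-host CD45.2 libraries, and 42.5 and 43.5 in the doubly deposited and the unassigned library. The CD8a tag had medians of 18, 13, 12 and 19 UMIs in CD8 T-like cells of the 4 labelled libraries, against 13, 12, 7 and 14 in CD4 T-like and 12, 10, 7 and 14 in B-like cells. The CD45 tag had a median of 1268 UMIs per kept cell in the doubly deposited library.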
